A study of Anguilla anguilla with 36 samples.

How the data were processed

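RNA was sequenced from intestine, liver and spleen of 12 European eels, at 6, 18 and 36 h after an injection of Aeromonas hydrophila or PBS, with 2 libraries in each of 18 groups (36 libraries). Per the labels, RNA was extracted with TRIzol and libraries were made with a TruSeq mRNA kit. The aligner, the assembler and the tool that counted reads are not given in the sources used here. Per the file headers, the authors deposited for each library a read count and an FPKM value (fragments scaled by feature length and library total) for each of 100741 assembled features. The count columns hold whole numbers with a different total in each library, and were used here. The FPKM columns deposited by the authors were used only to derive feature lengths (median 388 bp), and which total they divide by is not stated. The authors also deposited 9 comparison tables with the counts and FPKM of the features they selected, of which the table of intestine at 6 h holds 4 count columns and 3 FPKM columns. The values of these tables equalled those of the library files. The rule of selection is not given in the sources used here. Features with no count in any library numbered 7.

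Total counts per library lay between 16924178 and 26052274, and reads without molecular identifiers are not independent molecules. Groups were taken from the tissue, time and treatment in the titles. For the 2 libraries titled intestine 6 h Ah, the treatment label names the PBS control at 6 h, and the title was used. The replicate numbers of infected and PBS libraries were checked for pairing: the log2 difference of replicate 1 from replicate 2 in the infected group correlated with that in the PBS group at r = -0.321 to 0.0733, across features, over 9 comparisons, and no block was used. The same difference in 2 tissues of the same time and treatment correlated at r = 0.147 to 0.443 in 14 pairs without a library against its label, so these numbers were taken to mark the same fish. A fish block was tried in the tests between tissues, and its counts are given where it changed a call or moved a count.

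Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with default settings, quasi-likelihood F-test). Features with a Benjamini-Hochberg adjusted p under 0.05 were called. Each tissue had 1 fit of 12 libraries with 6 groups and 6 residual degrees of freedom, and the tests between tissues used 1 fit of all 36. Contrasts were infected against PBS at each time, the average of the 3 times, the difference of the effect between times or tissues, and time among PBS libraries. The features tested numbered 47248 in intestine, 36912 in liver, 50023 in spleen and 57832 in the fit of all libraries. The biological coefficient of variation was 0.553 in intestine, 0.634 in liver, 0.499 in spleen and 0.586 over all. These comparisons, their tests and the alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma voom (limma 3.58.1), DESeq2 size factors, upper-quartile or library-size scaling, no filter, at least 5 CPM in 2 libraries, a 2-fold threshold, other sets of libraries in the fit, blocks, and leaving out each library. Chosen after seeing the data were fits without the 2 libraries whose profile goes against their label, in which a lone library of a group is assumed to vary like the other groups.

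Tissue-enriched features were chosen after seeing the data as a replacement for gene lists. A feature was enriched in a tissue when it had at least 5 CPM there and over 20 times the level in each other tissue plus 0.05 CPM, in PBS libraries of the other times, without the 2 libraries against their label. The lists for a comparison therefore used no library of that comparison. The profile and the summed level of a library instead used lists set by all PBS libraries except the library itself, those of the same time and the library labelled liver 6 h PBS 2 included. They were tested against all other features with limma camera (correlation of 0.01, or estimated) and in themselves with limma fry, with p adjusted over the lists, tissues and times. Library measures were compared by exact permutation of treatment within time, two-sided, with 216 assignments and a family of 11 tests. The lists behind the profiles and sums stayed those of the real PBS libraries in this test. It was therefore repeated, as an alternative chosen after seeing the data, with lists and levels from PBS libraries of the other times that match their label, rebuilt for each assignment.

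The deposited files do not pair the feature IDs with genes, and 0 of 100741 IDs matched the reference table. The 35 gene lists fixed before the data were examined, the named marker check and the rule for naming genes could therefore not be applied. Instead 4 features were named after their values were seen, from those called in most comparisons, 2 that rose and 2 that fell. The pipeline was tested on simulated data with 200 changed features of above-median level, drawn around each feature's mean level with its fitted spread. A first version with folds of 2 and 4 alone recovered 0 of 100 features of each fold at 36 h, and the folds were then widened to 4, 16, 64 and 256. Python 3.11.15, numpy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the summaries and plots.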

Results

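RNA sequencing measured transcript levels in the intestine, liver and spleen of 12 European eels (Anguilla anguilla) after an intraperitoneal injection. Infected fish received Aeromonas hydrophila, a freshwater bacterium that causes septicaemia in fish, and control fish received phosphate-buffered saline (PBS). Tissues were taken at 6, 18 and 36 h, so that the 3 tissues, 3 times and 2 injections formed 18 groups of 2 libraries, each library from 1 fish. The comparisons asked how transcript levels in each tissue responded to the infection over time. Each library held a count for each of 100741 assembled transcript features, named only by assembly IDs. The deposited files do not pair these IDs with genes, and 0 of them matched the 31451 genes of the reference table. Groups of features were therefore defined by the tissue in which control fish expressed them. Total counts lay between 17889813 and 22187587 in intestine, 18964217 and 26052274 in liver, and 16924178 and 25787955 in spleen. A library detected between 34968 and 61876 features.

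Tissue-enriched features, set in PBS libraries, gave each library a profile of the 3 tissues. A profile is the median level of a tissue's features as a percentage of their level in the other PBS libraries of that tissue, with both the lists and the level set by all PBS libraries except the library itself. For liver these include the library labelled liver 6 h PBS 2. Profiles and summed levels are scaled by library total alone, without TMM. With lists and levels from PBS libraries of the other times that match their label, the same 34 libraries had the highest profile for their labelled tissue. In 34 of the 36 libraries the labelled tissue had the highest profile. The library labelled liver 6 h PBS 2 had an intestine profile of 93.3% and a liver profile of 3.12%. Its log2 CPM (read count scaled to an equal library total) correlated at r = 0.992 across features with the library of intestine 6 h PBS 2. The chi-square statistic per feature between these libraries was 4.61, against 30.6 to 167 within the 16 groups without a library against its label. The library labelled intestine 18 h Ah 2 had a liver profile of 28.0% and an intestine profile of 0%. With lists and levels from the other times its liver profile was 18.5%. It correlated most closely with liver 18 h Ah 1 (r = 0.969, chi-square 56.6 per feature). These 2 libraries stayed in the counts of the planned comparisons, and each count is also given without them, an alternative chosen after seeing the data. The group intestine 6 h Ah was formed by its titles, because the treatment label of its 2 libraries names the PBS control at 6 h. Their profile of intestine-enriched features (39.5% and 50.1%) lay below that of the 6 intestine PBS libraries (73.5% to 111%). The same values enter the infected group of the intestine profile test below, so they do not settle which label is right.

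**Figure D1:**
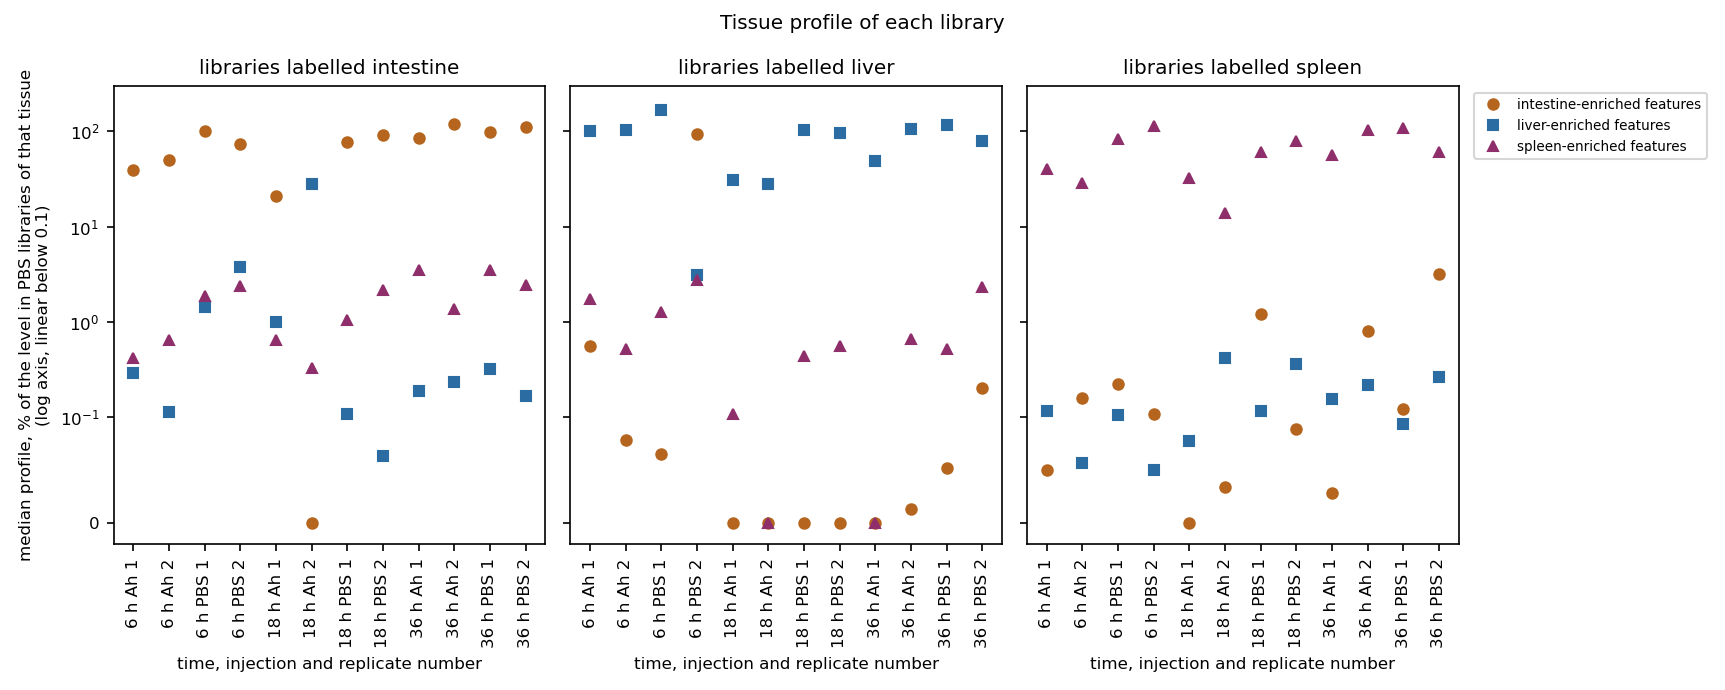
Tissue profile of the 36 libraries, by labelled tissue: each symbol is the median level of intestine-, liver- or spleen-enriched features in 1 library, as a percentage of PBS libraries of that tissue, on a log axis that is linear below 0.1. The libraries labelled liver 6 h PBS 2 and intestine 18 h Ah 2 carry the highest profile of another tissue (93.3% intestine and 28.0% liver).

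The spleen, the tissue with no library against its label, responded at 6 h and at 18 h. At 6 h 2786 features rose and 2062 fell, and at 18 h 4408 rose and 2889 fell. Spleen-enriched features fell in the median at both times, while their summed level did not fall at 6 h. The list for 6 h summed to 42052 and 37777 CPM in infected spleens, against 25049 and 32192 CPM in PBS spleens. The list for 18 h summed to 33571 and 32966 CPM, against 31260 and 42513 CPM. These sums were not tested. At 6 h 99 of 432 tested members fell and 33 rose, with a median log2 fold change of -1.0. At 18 h 103 of 456 fell and 35 rose, with a median of -1.11. Adjusted over the list alone, 140 and 133 fell at these times and 46 rose at each. Intestine-enriched features also had a low median in spleen at 18 h (-1.42 over 489 members, of which 7 fell and 5 rose). Their list did not pass limma camera (adjusted p = 0.0843), and its median was 0.05 without PBS replicate 1. The median profile of spleen-enriched features was 39.8% and 29.0% in the infected libraries at 6 h and 32.6% and 13.7% at 18 h, against 60.5% to 114% in the 6 PBS libraries. The group test against all other features (limma camera, preset correlation) gave an adjusted p of 3.86e-06 at 6 h and 0.000197 at 18 h. Neither call held with an estimated correlation (adjusted p = 0.944 at both times), and limma fry gave adjusted p of 0.0935 and 0.117. Over all 3 times, the profile was lower in infected spleens by an exact stratified permutation test (45.9% ± 31.6 against 84.7% ± 23.2, SD, n = 6 each, two-sided p = 0.0278, adjusted p = 0.0437 over 11 library measures). With the lists taken from the other times and rebuilt for each assignment, the exact permutation p was 0.0139. The profile is scaled by library total. Against TMM, that scaling shifted log2 fold changes in spleen by -0.46 at 6 h, -0.61 at 18 h and -0.16 at 36 h. The profile tests do not separate this shift from a change of the list. The counts of called features rested on all 4 libraries of a comparison. Under library-size scaling 1630 rose and 2963 fell at 6 h, and 1957 rose and 3734 fell at 18 h. At 6 h the counts with TMM scaling were 1282 without infected replicate 1, 1314 without infected replicate 2, 598 without PBS replicate 1 and 679 without PBS replicate 2. At 18 h they were 10113 without infected replicate 1, 1825 without infected replicate 2, 4360 without PBS replicate 1 and 359 without PBS replicate 2.

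Liver-enriched features rose in the infected spleen at 18 h, by a median log2 fold change of 0.82 over 234 members, of which 17 rose and 4 fell (camera adjusted p = 0.0119, adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.857). The summed level of liver-enriched features was 12850 and 15900 CPM in the 2 infected spleens at 18 h, against 715 to 2352 CPM in the 6 PBS spleens. Few members carried it: the 10 highest of the list for 18 h held 11881 of 12663 and 13802 of 15278 CPM. That list has 433 features, and the list behind the summed level has 350. The median liver profile of these infected spleens was 0.0769% and 0.418%, against 0.0499% to 0.359% in the PBS spleens. Across the 3 times the summed level, not the median profile, was higher in infected spleens by 1.98 on the log2 scale (exact stratified permutation test, two-sided p = 0.00926, the smallest that the 216 assignments allow, adjusted p = 0.0255, n = 6 each). With the lists rebuilt the summed level was higher by 2.08 (exact permutation p = 0.00463). The call of the list as a whole at 18 h was lost without infected replicate 2, where limma camera gave an unadjusted p of 0.0942 and the median difference was -0.72. It was also lost without PBS replicate 1 (unadjusted p of 0.0766, median difference 0.13). Under library-size scaling the median was 0.21. Infected replicate 2 had 32.5% of its counts in the 100 highest features, against 24.5% in the next infected spleen.

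In the intestine, with all libraries, 679 features rose and 354 fell at 6 h, where the infected group rests on the titles. At 18 h, also with all libraries, 5308 rose and 4304 fell. Without the 2 libraries against their label, 1980 rose and 1804 fell at 6 h, and 3354 rose and 1828 fell at 18 h, where 1 infected library remained. All 1033 features called at 6 h with every library were among the 3784 called without the 2, and at 18 h 4434 features were called both ways. In that reduced set intestine-enriched features fell as a group at 18 h. There 187 of 857 members fell and 11 rose, with a median log2 fold change of -1.61 (camera adjusted p = 3.84e-08, adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.0935). Adjusted over the list alone, 296 fell and 35 rose. The profile in the remaining infected library was 21.2%, against 77.9% and 92.1% in the PBS libraries. At 6 h 107 of 802 members fell and 36 rose, with a median of -0.33, and the group did not pass (camera adjusted p = 0.0761). Library-size scaling, which the profile also uses, gave that list a median of -0.92 at 6 h in the reduced set. Over the 3 times, the profile was lower in infected intestines (52.8% ± 43.9 against 92.7% ± 14.5, SD, n = 6 each, exact stratified permutation test, two-sided p = 0.0278, adjusted p = 0.0437). It remained lower without the library against its label (63.4% ± 39.7, n = 5, exact p = 0.0278). With the lists rebuilt the exact permutation p was 0.0324, and 0.0278 without that library. Under library-size scaling of all libraries edgeR called 0 at 6 h, and 1663 rose and 8071 fell at 18 h. The counts at 6 h with TMM scaling moved with each of the 4 libraries. They were 0 without infected replicate 1, 439 without infected replicate 2, 0 without PBS replicate 1 and 0 without PBS replicate 2. Without the 2 libraries against their label as well, they were 155, 3162, 3 and 0 in the same order. At 18 h the counts were 12899 without infected replicate 1, 5182 without infected replicate 2, 1292 without PBS replicate 1 and 1452 without PBS replicate 2. In the reduced set the 18 h counts were 747 and 540 without PBS replicates 1 and 2. Where a leave-out gave 0 in edgeR at 6 h, only this tool was run.

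Liver-enriched features had medians of opposite sign in the intestine at 6 h and 18 h, in the set without the 2 libraries. At 18 h 80 of 343 members rose and 0 fell, with a median log2 fold change of 2.48 (camera adjusted p = 9.56e-19, adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.0935). Their summed level in the remaining infected library was 37664 CPM, against 1578 and 830 CPM in the PBS libraries, and their median profile was 0.999%, against 0.107% and 0.0628%. At 6 h 30 of 326 members fell and 3 rose, with a median of -2.54 (camera adjusted p = 1.21e-15, adjusted p = 0.944 with an estimated correlation). The 2 PBS intestines at 6 h had the highest liver profiles of the intestine libraries that match their label, 1.42% and 3.71%. The infected intestines at 6 h (0.290% and 0.111%) lay within the range of the PBS intestines at 18 h and 36 h (0.0628% to 0.317%). The fall at 6 h therefore went with high levels in the PBS libraries of that time, and a response to infection is not shown by it. Across the 3 times the summed level did not pass between infected and PBS intestines (log2 difference 2.56 with all libraries and 1.97 without the library against its label, exact stratified permutation p = 0.111 for both, and exact p = 0.0880 and 0.111 with the lists rebuilt).

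The liver response was called at different times depending on the 2 libraries. With all libraries 512 features rose and 297 fell at 6 h, and 0 were called at 18 h by edgeR, where 8127 had an unadjusted p under 0.05, DESeq2 called 4826 and limma voom called 1. With the 2 libraries against their label left out, 275 rose and 227 fell at 6 h, against 1 remaining PBS library, and 1168 rose and 1600 fell at 18 h. Of the features called at 6 h, 282 were called both ways. At 18 h liver-enriched features fell as a group in the reduced set, with 106 of 433 members lower, 15 higher and a median log2 fold change of -1.29 (camera adjusted p = 3.79e-08, adjusted p = 0.944 with an estimated correlation, fry adjusted p = 0.219). Adjusted over the list alone, 151 fell and 25 rose. The liver profile was 30.7% and 28.0% in the infected libraries at 18 h and 103% and 97.3% in the PBS libraries. The summed level of the list was instead higher, at 498860 and 403380 CPM in the infected libraries against 329930 and 371830 CPM in the PBS libraries. Its 10 highest members held 370820 and 277620 CPM, against 147780 and 161500 CPM. These sums were not tested. At 6 h 7 members fell and 4 rose of 366, with a median of 0.13 (camera adjusted p = 0.430). The infected livers at 6 h had profiles of at least 102%, below the 169.0% of the remaining PBS library of that time. With lists and levels from the other times these profiles were 94.9% and 101.1%, against 143.2% in that PBS library. Under library-size scaling, which the profiles also use, the median of the liver list at 6 h was -0.55. With 1 PBS library left, a fall at 6 h is neither shown nor excluded. Over the 3 times, the liver profile did not differ with all libraries (70.3% ± 38.3 against 94.5% ± 54.2, SD, n = 6 each, exact stratified permutation test, p = 0.417). It was lower without the library against its label (70.3% ± 38.3, n = 6, against 113% ± 34.1, n = 5, exact p = 0.0185). With the lists rebuilt the exact permutation p was 0.699 with all libraries and 0.0370 without that library. Under library-size scaling of all libraries 260 rose and 1848 fell at 6 h. The counts rested on single libraries. At 6 h they were 0 without infected replicate 1, 0 without infected replicate 2, 4732 without PBS replicate 1 and 502 without PBS replicate 2. At 18 h in the reduced set they were 426 without infected replicate 1, 312 without infected replicate 2, 155 without PBS replicate 1 and 321 without PBS replicate 2. Where a leave-out gave 0 at 6 h, only edgeR was run.

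**Figure D2:**
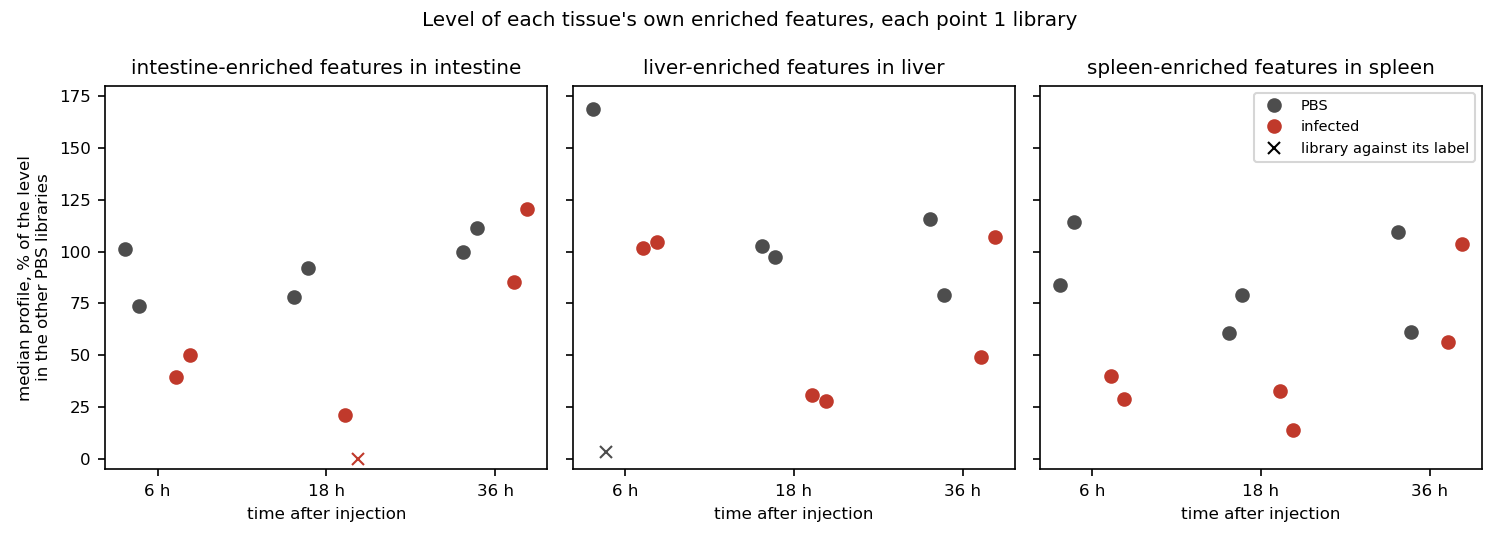
Median level of each tissue's own enriched features in each library, as a percentage of their level in the other PBS libraries of that tissue (linear axis, PBS in grey, infected in red, crosses for the 2 libraries against their label). Infected libraries at 18 h that match their label lie between 13.7% and 32.6%.

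At 36 h no feature passed in any tissue with edgeR under its default filter and 1 fit per tissue, with all libraries or without the 2. Without a filter edgeR called 627 in intestine, 242 in liver and 2028 in spleen, and with 34 libraries in 1 fit 0, 2 and 2. Intestine-enriched features had a median log2 fold change of 0.05 over 818 members, and spleen-enriched features one of -0.06 over 527 members. Liver-enriched features had a median of 0.19 and a mean of 0.03 over 376 members, of which 0 were called over all features by edgeR and 1 rose when adjusted over the list alone. That list passed with camera (adjusted p = 0.00366, adjusted p = 0.944 with an estimated correlation). Its median was -0.40 under library-size scaling. The call was lost without infected replicate 2 (unadjusted limma camera p of 0.717, median difference -0.09) and without PBS replicate 2 (unadjusted p of 0.0603, median difference -0.45). The numbers of features with an unadjusted p under 0.05 were 1397 in intestine, 1733 in liver and 5074 in spleen, and 2397 and 2428 in intestine and liver without the 2 libraries. About 1 in 20 of the tested features would have such a p without any effect. With all libraries the intestine and liver counts lay below that share and the spleen count above it. Without the 2 libraries the intestine count lay below it and the liver count above it. DESeq2 called 37, 78 and 1056 features in intestine, liver and spleen, and 142 and 199 in the reduced sets of intestine and liver. limma voom called 0 in each tissue with all libraries, and 0 in intestine and 1 in liver in the reduced sets. Leaving out PBS replicate 1 of the spleen gave 61 calls, and leaving out infected replicate 2 of the liver in the reduced set gave 20. In simulated data at this size, for features of above-median level, edgeR recovered 0%, 2% and 12% of 4-fold changes at 36 h in intestine, liver and spleen with all libraries, 62%, 48% and 94% of 16-fold changes, and 88%, 82% and 98% of 64-fold changes. Without the 2 libraries it recovered 10% and 8% of 4-fold and 82% and 80% of 16-fold changes in intestine and liver.

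**Figure D3:**
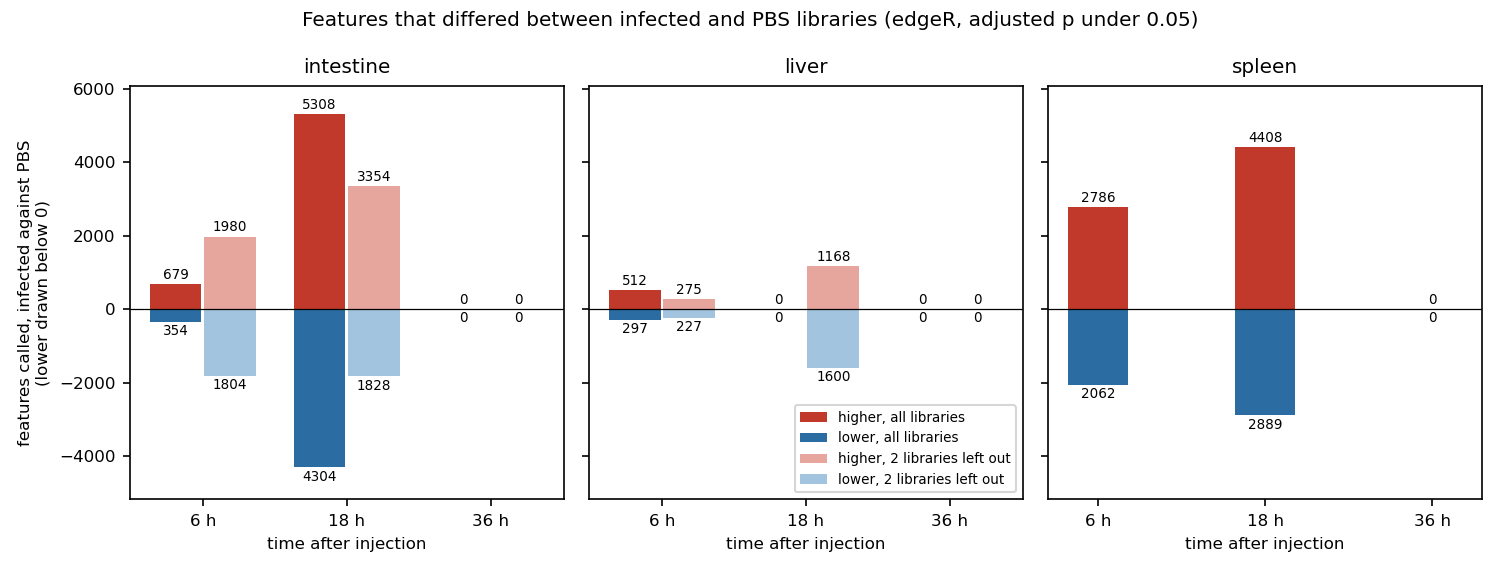
Number of features that differed between infected and PBS libraries (edgeR, adjusted p under 0.05) by tissue and time, with higher features above and lower features below 0. Dark bars use all libraries, and pale bars leave out the 2 libraries against their label (for example, 0 against 2768 calls in liver at 18 h).

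Features that rose or fell at 6 h kept part of their difference at 18 h. In the spleen the 2786 features that rose at 6 h had a median log2 fold change of 1.28 at 18 h and 0.64 at 36 h, and 962 of them were called higher again at 18 h and 20 lower. The 2062 that fell had medians of -1.18 and -0.18, and 557 were called lower again at 18 h and 40 higher. In the intestine, without the 2 libraries, the 1980 features that rose had medians of 1.59 and 0.44 at the later times and the 1804 that fell had medians of -1.44 and -0.23. In the liver the 275 that rose had medians of 1.90 and 0.72. The 36 h medians rested on infected replicate 1. On the features called at 6 h, the median signed difference from PBS at 36 h was 0.54 in infected replicate 1 and 0.07 in replicate 2 of the intestine, 0.99 and -0.07 in liver, and 0.67 and 0.10 in spleen. The reverse held as well: the 1168 features that rose in the liver at 18 h had a median of 2.08 at 6 h, while the 1600 that fell there had one of -0.62. These values at the other times share no library with the comparison that selected the features.

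**Figure D4:**
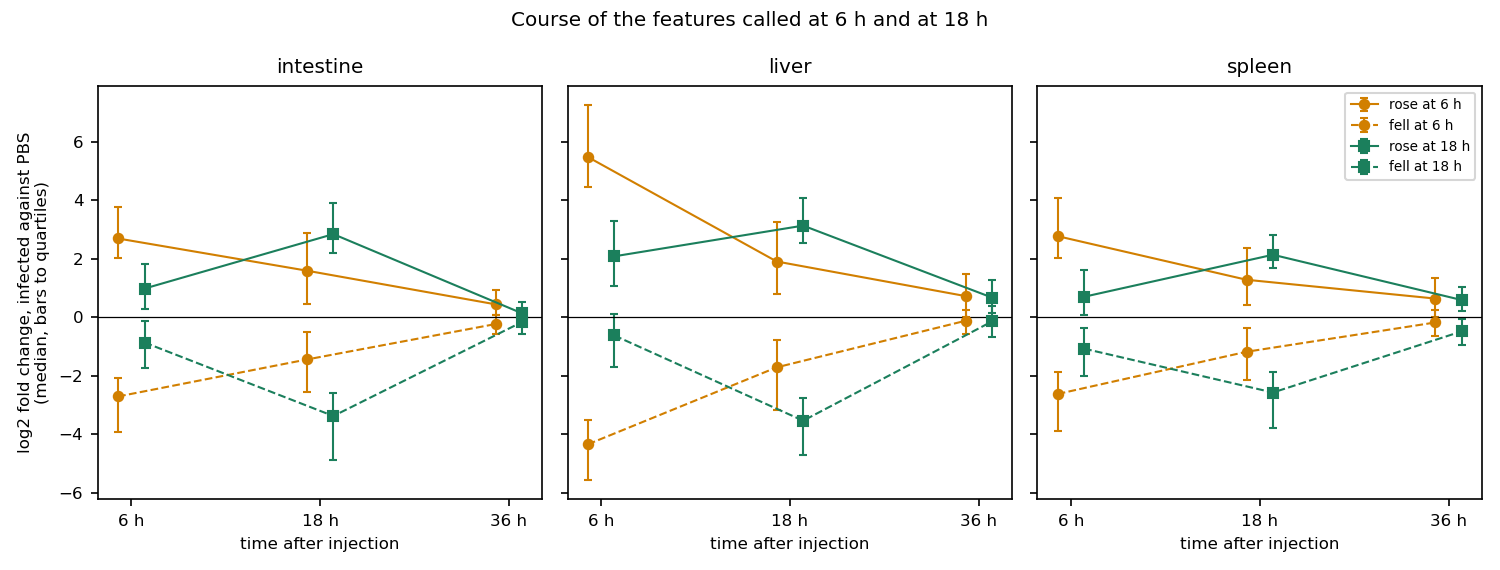
Median log2 fold change (infected against PBS, bars to the quartiles) at 6, 18 and 36 h of the features called at 6 h (circles) and at 18 h (squares), without the 2 libraries against their label, solid lines for features that rose and dashed lines for features that fell. Values at the time of the call are raised by the selection, and spleen features that rose at 6 h have medians of 1.28 at 18 h and 0.64 at 36 h. The 36 h values average 2 infected libraries that differ, for example 0.99 and -0.07 in liver for features called at 6 h.

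The test of whether the infection effect differed between the 3 times called 308 features in the spleen. In the intestine and the liver edgeR called 0, where 10847 and 5111 features had an unadjusted p under 0.05, DESeq2 called 7019 and 1835, and limma voom called 0 in both. In the set without the 2 libraries, edgeR again called 0 in intestine and liver (unadjusted p under 0.05 for 11090 and 5716, DESeq2 6031 and 1922, limma voom 0 in both). Each library of the spleen moved the count of 308. It became 1, 1, 0 and 0 without infected replicates 1 and 2 and PBS replicates 1 and 2 of 6 h, 3212, 725, 0 and 0 without those of 18 h, and 121, 0, 182 and 28 without those of 36 h. The intestine count rose from 0 to 6090 without infected replicate 1 of 18 h, and the liver count from 0 to 2616 without PBS replicate 1 of 6 h. In the reduced sets, the intestine count was 433 and 4 without infected replicates 1 and 2 of 36 h and 1 without PBS replicate 1 of 6 h. The reduced liver count was 3 and 2 without infected replicates 1 and 2 of 18 h, 935 without infected replicate 1 of 36 h and 6 without PBS replicate 1 of 36 h.

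Averaged over the 3 times, infection raised 6182 features and lowered 5345 in the spleen, raised 4670 and lowered 4155 in the intestine, and raised 1934 and lowered 1177 in the liver. In the reduced set, the averaged counts were 4235 and 4205 in the intestine and 2415 and 1850 in the liver. Under library-size scaling of all libraries the averaged counts were 3104 and 8635 in the spleen, 1486 and 8324 in the intestine and 575 and 4485 in the liver. In the spleen the count of 11527 became 5775 without infected replicate 1 of 36 h, 7212 and 7680 without PBS replicates 1 and 2 of 36 h, 6765 without infected replicate 2 of 6 h, and 6659 and 6876 without PBS replicates 1 and 2 of 6 h. In the intestine the count of 8825 became 4341 and 4161 without PBS replicates 1 and 2 of 18 h, 2928 without infected replicate 1 of 36 h, 3216 and 4119 without PBS replicates 1 and 2 of 36 h, 4087 without infected replicate 1 of 6 h, and 3459 and 4753 without PBS replicates 1 and 2 of 6 h. In the reduced set, the intestine count of 8440 became 4656 without infected replicate 1 of 36 h, 4576 and 5549 without PBS replicates 1 and 2 of 36 h, and 5134 without PBS replicate 1 of 6 h. In the liver the count of 3111 became 1649 and 709 without infected replicates 1 and 2 of 18 h, 0 and 0 without the PBS replicates of 18 h, 620 without infected replicate 1 of 36 h, 489 and 604 without the PBS replicates of 36 h, 726 and 396 without the infected replicates of 6 h, and 5258 without PBS replicate 1 of 6 h, with only edgeR run. In the reduced set, the liver count of 4265 became 2514 without infected replicate 2 of 18 h, 1917 and 2165 without the PBS replicates of 18 h, 2638 and 7682 without the infected replicates of 36 h, 2532 without PBS replicate 1 of 36 h, and 2209 and 1679 without the infected replicates of 6 h.

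Some features responded in several tissues at the same time, in the set without the 2 libraries. At 6 h 741 features rose in both intestine and spleen, where 110 would be shared by independent lists, and 21 moved oppositely. At 18 h 2093 rose in both (324 for independent lists), 702 rose in liver and spleen (134) and 627 in intestine and liver (101). At 18 h 386 fell in intestine and spleen (95.6 for independent lists), 285 in liver and spleen (84.4) and 230 in intestine and liver (61.5). With all libraries 347 rose in intestine and spleen at 6 h (39.5 for independent lists, 10 oppositely) and 2760 at 18 h (537 for independent lists, 14 oppositely). No overlap with liver could be counted at 18 h with all libraries, because edgeR called 0 there (8127 at an unadjusted p under 0.05, DESeq2 4826, limma voom 1). Across the 35334 features tested in all tissues, fold changes of 2 tissues at the same time correlated at Pearson r = 0.276 to 0.614 (median 0.490 over 9 pairs). Fold changes of 1 tissue at 2 times correlated at 0.106 to 0.417, and of 2 tissues at 2 times at 0.0535 to 0.347. These correlations run across features, which are not independent replicates. The tissues of 1 time came from the same fish, so that part of the overlap and correlation at the same time may come from the shared fish. Comparisons at 2 times shared no fish.

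**Figure D5:**
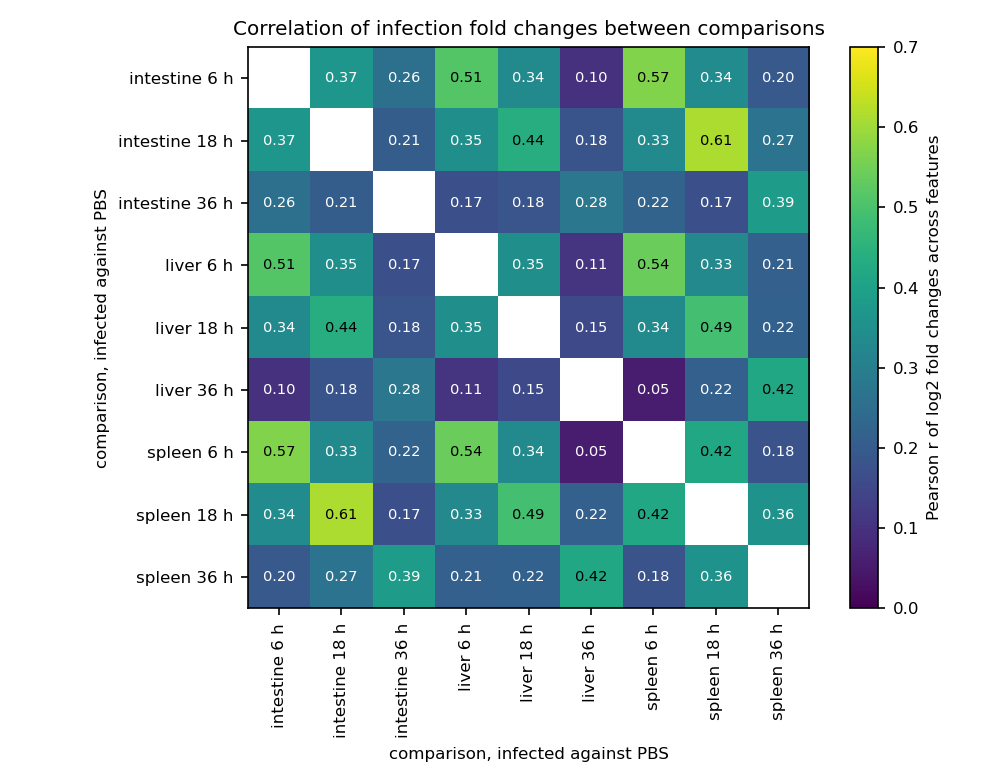
Pearson correlation across 35334 features of the log2 fold changes (infected against PBS) between the 9 comparisons of tissue and time, without the 2 libraries against their label; both axes list the comparisons and the colour gives r. Pairs of tissues at the same time reach 0.614 (intestine and spleen at 18 h), and pairs that differ in tissue and time reach 0.347.

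The test of whether the infection effect differed between the 3 tissues called 69 features at 6 h and 132 at 18 h. With these 2 libraries left out, it called 203 and 575, and with the fish as a block in that set 1169 and 2729. At 36 h edgeR called 0, with 1306 features at an unadjusted p under 0.05, 16 calls by DESeq2 and 1 by limma voom. The 1306 are fewer than the 1 in 20 of tested features that would have such a p without any effect. In that reduced set, edgeR called 0 at 36 h (2058 at an unadjusted p under 0.05), and 5 with the fish block. The tissue counts rested on single libraries. At 6 h they became 32, 49, 18 and 24 without infected replicates 1 and 2 and PBS replicates 1 and 2 of the intestine, 35, 39, 553 and 79 without those of the liver, and 13, 7, 18 and 4 without those of the spleen. At 18 h they became 1030, 150, 22 and 15 for the intestine, 14, 10, 0 and 0 for the liver and 77, 4, 1 and 1 for the spleen, in the same order.

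In the set without the 2 libraries, an alternative chosen after seeing the data, 28 of the 35334 features tested in all tissues rose in 6 comparisons and 19 fell in 5. No feature could be called in more than 6 of the 9, because edgeR called 0 at 36 h, where the unadjusted counts and those of the other tools are given above. The 4 features named here were chosen after seeing the data, from those called most often. Each SE given for them is the log2 fold change divided by the square root of the quasi-likelihood F statistic. The spread in that statistic is estimated over all libraries in the fit of the tissue. The feature c237471.graph_c0 (1975 bp) rose in spleen at 6 h by 6.06 ± 0.54 (log2, SE, 2 against 2 libraries, edgeR adjusted p = 0.00143), from 1.31 and 2.02 CPM to 71.0 and 90.9 CPM. It rose by 6.10 ± 0.87 in intestine at 6 h (adjusted p = 0.0115). In spleen its log2 fold change was 2.93 at 18 h (adjusted p = 0.00618) and 2.15 at 36 h (adjusted p = 0.209). The feature c211306.graph_c0 (980 bp) rose by 5.52 ± 0.59 in spleen at 6 h (adjusted p = 0.00221) and by 6.40 ± 0.87 in intestine at 6 h (adjusted p = 0.0109). The feature c246694.graph_c0 (2059 bp) fell in spleen at 6 h, with a log2 fold change of -5.43 ± 0.77 (adjusted p = 0.00413) and levels of 2.40 and 2.22 CPM against 168 and 106 CPM. The feature c266078.graph_c0 (1854 bp) fell in spleen at 6 h and 18 h, with log2 fold changes of -4.63 ± 0.67 and -4.81 ± 0.67 (adjusted p = 0.00434 and 0.00472). Each of the 4 calls at 6 h in spleen, and that of c266078.graph_c0 at 18 h, held in 15 of 15 alternatives. The intestine calls of c237471.graph_c0 and c211306.graph_c0 at 6 h, from the set without the 2 libraries, held in 14 and 15 of 22 alternatives with log2 fold changes of 5.19 to 6.67 and 5.52 to 6.95. In that set the call of c237471.graph_c0 was lost without infected replicate 1 (edgeR adjusted p = 0.0504), and those of c237471.graph_c0 and c211306.graph_c0 without PBS replicate 1 (0.0823 and 0.0776) and without PBS replicate 2 (0.0655 and 0.0619). The call of c237471.graph_c0 in spleen at 18 h held in 12 of 15 alternatives. It was lost without PBS replicate 2 of 18 h (edgeR adjusted p = 0.0641), with all 36 libraries in 1 fit (0.0556) and with only the 4 libraries of the comparison (0.0565).

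Infected libraries detected fewer features. At equal depth, infected spleens detected 55344 ± 4099 features (SD, n = 6) against 59271 ± 1086 in PBS spleens (exact stratified permutation test, two-sided p = 0.00926, adjusted p = 0.0255). Infected livers detected 40266 ± 5327 against 46882 ± 8159 (exact p = 0.00926, adjusted p = 0.0255), and infected intestines 51799 ± 7159 against 57119 ± 2566 (exact p = 0.0185, adjusted p = 0.0407). Without the libraries against their label the difference was -5274 features in liver and -4039 in intestine (exact p = 0.0185 for both). The 100 highest features took 58.2% ± 7.30 of the counts in infected livers and 47.0% ± 11.3 in PBS livers (exact p = 0.00926, adjusted p = 0.0255), a difference of 7.67 points without the library against its label (exact p = 0.0185). In intestine and spleen this share did not pass (adjusted p = 0.0637 and 0.377).

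PBS libraries also differed between times. The test over 6, 18 and 36 h called 342 features in spleen, 25 in liver and 2 in intestine, and 194 in liver and 103 in intestine without the 2 libraries. The spleen count was 16, 65, 89, 16 and 49 without PBS replicate 1 of 18 h, PBS replicate 2 of 18 h, PBS replicate 2 of 36 h, PBS replicate 1 of 6 h and PBS replicate 2 of 6 h. The liver count was 0 without either PBS library of 18 h or either of 36 h, 4740 without PBS replicate 1 of 6 h and 194 without PBS replicate 2 of 6 h. The intestine count was 0 without any 1 of its 6 PBS libraries. In the reduced sets, the liver count was 28 and 31 without PBS replicates 1 and 2 of 18 h, and 112 and 83 without those of 36 h. The reduced intestine count was 0 and 9 for 18 h, 0 and 0 for 36 h, and 6 and 0 for 6 h, in the same order. For the leave-outs at 0 only edgeR was run.

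The authors' deposited tables listed 1768, 1755 and 89 features for intestine at 6, 18 and 36 h, 521, 2025 and 26 for liver, and 4332, 1415 and 378 for spleen. These tables hold counts and FPKM and give no direction, so it was taken from the mean CPM of the same libraries. In the spleen, edgeR called 2675 of the 4332 listed at 6 h and 1340 of the 1415 listed at 18 h in that direction. In the intestine it called 568 of 1768 at 6 h and 1689 of 1755 at 18 h with all libraries, and 1373 and 1349 without the 2. In the liver it called 319 of 521 at 6 h and 0 of 2025 at 18 h with all libraries, and 164 and 1600 without the 2. At 36 h edgeR called 0 of the features in the authors' deposited table for each tissue.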

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

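The tests of the 2 libraries against their label, of abundant features, of RNA from another tissue and of liver carry-over were chosen after the result was seen, and the matched-list test was planned before. Single libraries stood apart from the others of their tissue and treatment in 3 measures. Among 6 infected intestines the total count of 18 h replicate 1 was 19307467, below the next at 21405205. The library labelled intestine 18 h Ah 2 had 63.4% of its counts in the 100 highest features, against 36.5% in the next, and spleen 18 h Ah 2 had 32.5%, against 24.5%. Of 24 sets of 6 libraries tested, about 1 in 20 would stand out by chance. The effect of infection differed between tissues for 132 features at 18 h and 69 at 6 h, and over time for 308 features in spleen, by tests of the difference itself.

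The library labelled liver 6 h PBS 2 had an intestine profile and the library labelled intestine 18 h Ah 2 a liver profile. A swap of the 2 with each other is argued against, because the smaller gap between the highest r to any library and r to the remaining library of the other's group was 0.0824. A mixture stays open for the first, whose liver profile of 3.12% lay above the 0.0628 to 1.42 of other intestine libraries but below the 3.71 of intestine 6 h PBS 2, its near copy, and is argued against for the second, whose intestine profile of 0% lay within 0 to 0.549 in liver libraries. For the first, 1 RNA sample under 2 labels may be the source, since its chi-square per feature against intestine 6 h PBS 2 was 4.61, below every pair of libraries of a group. For the second that value was 56.6, within the range of such pairs, so a wrong label or an exchange with a library outside the series stays open.

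Tissue-enriched features fell in infected spleen at 6 h and 18 h and in intestine and liver at 18 h, in the libraries that match their label, by limma camera with the preset correlation; these calls were lost with an estimated correlation (adjusted p = 0.944 for all 4) and with limma fry (adjusted p = 0.0935 to 0.219). Features of like level and length did not fall alike, since the percentile of the list medians among matched random lists was 0, although a list with a median of -0.06 (spleen 36 h) also had percentile 0, because random lists of independent features vary little. A few abundant features taking most of the counts is argued against by a list median 0.96 log2 units or more below that of other features (-0.96 at the nearest). RNA from another of the sampled tissues is argued against by its highest profile of 0.999%. These falls are of the list medians, and the summed levels in spleen at 6 h and in liver at 18 h did not fall. Lower expression in the tissue, loss of cells that carry these features and arrival of cells of a type not sampled stay open, as untested.

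Liver-enriched features had summed counts of up to 37664 CPM in the infected intestine and spleen libraries that match their label. Liver RNA carried over from infected fish of the same time would bring a median liver profile with its sum, and the observed profile was 0.0579 to 0.536 of that one in the 11 libraries. The ratio does not subtract the PBS level. The 0.536 came from intestine 36 h Ah 2, whose sum of 2616 CPM lay near the 2370 and 1990 CPM of its PBS libraries. At 18 h, where sums were raised, the ratio was 0.410 in intestine Ah 1 and 0.0924 and 0.406 in spleen Ah 1 and 2. Carry-over and expression in the tissue itself cannot be told apart, because the ratio passed the bound against carry-over in some of these libraries but not in others of the same groups, and reached the bound for it in none. In intestine 18 h Ah 1 the 10 highest members of the list for 18 h held 34195 of its 37644 CPM (this list has 433 features, and the list behind the sum of 37664 has 350), while 80 of 343 tested members rose and 0 fell. Libraries of other fish may decide it.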

How the results depend on the processing

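Chosen after seeing the data were all alternatives without the 2 libraries against their label, with 34 libraries in 1 fit, and for the tissue-enriched lists and named features. Counts below are called features. No call of the 4 named features reversed, but c266078.graph_c0, not called at 36 h, changed sign there in intestine, liver and spleen (-1.55 to 0.10, -1.74 to 0.38 and -1.68 to 0.44). More features rose than fell with TMM in the averaged counts, intestine and spleen at 18 h and liver and spleen at 6 h, and more fell than rose there under library-size scaling. Of the tissue-enriched lists that passed, the medians of 4 changed sign. That of intestine-enriched features in liver at 6 h (1.36) was -4.02 with all libraries. That of liver-enriched features in liver at 36 h (0.19) was -0.45 to 0.75 with 1 library left out (-0.09 without infected replicate 2, -0.45 without PBS replicate 2) and -0.40 under library-size scaling. That of liver-enriched features in spleen at 18 h (0.82) was -0.72 to 1.62 (-0.72 without infected replicate 2). That of intestine-enriched features in spleen at 36 h (-1.28) was -2.19 to 0.54 (0.54 without PBS replicate 2). Medians of lists that did not pass changed sign too, for example intestine-enriched features in intestine at 36 h (-0.35 to 0.39 with 1 library left out). Under DESeq2 size factors and upper-quartile scaling 21 of 21 counts, and under a 2-fold threshold 9 of 9, stayed within 1.5 times. The 2-fold threshold could hardly move a count. It was already passed by 4847 of 4848 calls in spleen at 6 h, 7275 of 7297 at 18 h and all calls elsewhere, and a count of 0 stayed 0. For the counts that moved, the cause was not tested, except that leaving out libraries leaves fewer of them. The gene list tests and the alternatives for named genes by rule were not run, since no ID matched a gene.

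DESeq2 gave 7075 for the averaged effect in liver, 3022, 16 and 1638 between tissues at 18, 36 and 6 h, and 7019, 1835 and 6023 over time in intestine, liver and spleen. For infection it gave 37 in intestine at 36 h and 6495 at 6 h, 4826 in liver at 18 h, 78 at 36 h and 4952 at 6 h, and 11832 in spleen at 18 h, 1056 at 36 h and 8802 at 6 h. Between PBS times it gave 1519, 2509 and 3787 in intestine, liver and spleen. limma voom gave 271, 1 and 500 between tissues at 18, 36 and 6 h, 1730 in intestine at 6 h, 1 and 1961 in liver at 18 and 6 h, and 6 between PBS times in intestine. In simulated data with infection changes at 36 h DESeq2 made 75 to 106 false calls among 243 to 259 in the infection test and 76 to 141 among 210 to 278 in the test over time.

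Without a filter the counts were 5902 (averaged, liver), 3284, 440 and 3124 (between tissues at 18, 36 and 6 h), 7576, 2727 and 7106 (over time in intestine, liver and spleen), 627 and 6156 (intestine 36 and 6 h), 3751, 242 and 4554 (liver 18, 36 and 6 h), 2028 and 8674 (spleen 36 and 6 h) and 2857, 4302 and 5150 (PBS times in intestine, liver and spleen). With at least 5 CPM in 2 libraries they were 611 and 193 (between tissues at 18 and 6 h), 345 and 1351 (over time in intestine and spleen), 1624 (intestine 6 h), 1322 and 1555 (liver 18 and 6 h) and 67 and 816 (PBS times in liver and spleen).

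Library-size scaling gave 5060 (averaged, liver), 8 and 8 (between tissues at 18 and 6 h), 205 (over time, spleen), 0 (intestine 6 h), 2108 (liver 6 h), and 0 and 1 (PBS times in intestine and liver). It moved the median log2 fold change of all features in intestine at 18 h from -0.29 to -1.26, and in spleen at 18 h from -0.16 to -0.70. The replicate number is no pair in these data (the check is in the description of the processing), and as a block it gave 2033 (averaged, liver), 18 (over time, spleen), 0 (intestine 6 h), 283 (liver 6 h), and 0, 5 and 159 (PBS times in intestine, liver and spleen). The same difference between replicates 1 and 2 correlated at -0.321 to 0.0733 between infected and PBS groups.

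All 36 libraries in 1 fit gave 2010 (intestine 6 h), 4613 and 5821 (liver 18 and 6 h) and 3065 and 1778 (spleen 18 and 6 h). All 34 libraries in 1 fit gave 4108 and 3320 (intestine 18 and 6 h), 5949, 2 and 3173 (liver 18, 36 and 6 h) and 4418, 2 and 2968 (spleen 18, 36 and 6 h). Only the 4 libraries of a comparison gave 0 (intestine 18 h), 3617 and 0 (liver 18 and 6 h) and 108 and 9917 (spleen 18 and 6 h).

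Without the 2 libraries against their label the counts were 575 and 203 (between tissues at 18 and 6 h), 5182 and 3784 (intestine 18 and 6 h), 2768 and 502 (liver 18 and 6 h) and 103 and 194 (PBS times in intestine and liver). With DESeq2 in that set they were 6847 (averaged, liver), 6031 and 1922 (over time in intestine and liver), 142 and 8462 (intestine 36 and 6 h), 5732, 199 and 2949 (liver 18, 36 and 6 h) and 2450 and 1617 (PBS times). With limma voom in it they were 5015 (averaged, liver), 3499 and 2854 (intestine 18 and 6 h), 2375, 1 and 2014 (liver 18, 36 and 6 h) and 37 and 911 (PBS times). With the fish block in it they were 2729, 5 and 1169 between tissues at 18, 36 and 6 h.

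Leaving out 1 library, with or without the 2, gave ranges of 2928 to 13066, 0 to 7682 and 5775 to 14429 for the averaged effect in intestine, liver and spleen. Between tissues they were 0 to 1030 at 18 h and 4 to 553 at 6 h, and over time 0 to 6090, 0 to 2616 and 0 to 3212 in intestine, liver and spleen. For infection they were 540 to 12899 and 0 to 3162 (intestine 18 and 6 h), 0 to 426, 0 to 20 and 0 to 4732 (liver 18, 36 and 6 h), and 359 to 10113, 0 to 61 and 598 to 1314 (spleen 18, 36 and 6 h). Between PBS times they were 0 to 9, 0 to 4740 and 16 to 297 in intestine, liver and spleen. Where a range starts at 0, edgeR was the tool and no other was run on those sets. Of simulated changes at 36 h, with all libraries, edgeR recovered 0%, 2% and 12% at 4-fold, 62%, 48% and 94% at 16-fold and 88%, 82% and 98% at 64-fold in intestine, liver and spleen. Without the 2 libraries it recovered 10% and 8% at 4-fold, 82% and 80% at 16-fold and 100% and 98% at 64-fold in intestine and liver.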

Other observations

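The test of the 36 h replicates was chosen after the result was seen, and the splits of the libraries were planned before. In the infected 36 h libraries, replicate 1 had the higher median signed difference from PBS on the features called at 18 h in all 3 tissues: 0.40 against -0.14 log2 units in intestine, 1.01 against -0.23 in liver and 0.82 against 0.24 in spleen. On the features called at 6 h the values were 0.54 against 0.07, 0.99 against -0.07 and 0.67 against 0.10. The 2 PBS libraries of 36 h also differed from each other on the features called at 18 h. Their median signed difference was 0.20 log2 units in intestine, 0.30 in liver and 0.09 in spleen for the higher PBS library against the other. The fish of replicate 1 may have still carried the earlier response and the fish of replicate 2 less of it, which 3 of 3 tissues showed; the tissues of a fish are not independent, and there was 1 fish of each kind.

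Treatment was reassigned within time in 40 of the 108 possible splits of the 12 libraries of each tissue, the real one included, and the averaged infection effect was refitted. In each tissue 1 of the 40 splits, the real one, gave as many features, which argues against chance without excluding it. The real split was always among the 40, the remaining possible splits were not run, and the tissues came from the same fish. The intestine and liver fits held the libraries against their label. The real counts were 8825 in intestine, 3111 in liver and 11527 in spleen, and the highest of the other splits gave 8052, 3082 and 7814. Each of these kept the labels at 2 of the 3 times. Among splits that did not, the highest counts were 1, 0 and 6.

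Other lists passed the set test with the preset correlation, and each moved with single libraries. Levels were low over the full lists. In liver at 6 h the median member of the intestine list had 0.229 and 0.0516 CPM, against 0.0527 CPM in PBS replicate 1. That of the spleen list had 0.321 and 0.103 CPM, against 0.211 CPM. In spleen at 36 h the median member of the intestine list had 0.0444 and 0.381 CPM, against 0.106 and 1.41 CPM in PBS libraries. Intestine-enriched and spleen-enriched features had medians of 1.36 and 1.15 log2 units in infected liver at 6 h against 1 PBS library (limma camera adjusted p = 0.00048 and 5.21e-05), where 4 of 427 members rose and 2 fell, and 5 of 271 rose and 0 fell. Without infected replicate 1 these medians were 0.17 and 0 (unadjusted limma camera p of 0.0835 and 0.0153), and under library-size scaling 0.68 and 0.47. With all libraries, the one labelled liver 6 h PBS 2 included, the intestine list went the other way (median -4.02, 415 of 429 members lower, limma camera adjusted p = 1.33e-08, adjusted p = 0.960 with an estimated correlation), and the spleen list had a median of 0.75. Intestine-enriched features had a median of -1.28 in infected spleen at 36 h (limma camera adjusted p = 0.000119), where edgeR called 0 of 529 members, over all features or over the list alone. Without PBS replicate 2 that list was called higher, not lower (median 0.54, unadjusted limma camera p of 0.000371), and without infected replicate 1 it did not pass (median -0.19, unadjusted limma camera p of 0.15). The summed level of intestine-enriched features was 4938 CPM in PBS replicate 2 and 609 CPM in PBS replicate 1, so the direction in spleen at 36 h is not settled. None of these calls held with an estimated correlation (adjusted p = 0.944).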
